A study of Drosophila melanogaster with 6 samples.

How the data were processed

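RNA-seq was done on GFP-positive intestinal progenitor cells sorted from adult female flies. Per the labels' protocols, each replicate began with the gastrointestinal tracts of 100 flies reared at 29 °C for 6 days, which were dissociated with elastase, and 30000 to 50000 GFP-positive cells were sorted by flow cytometry. Total RNA was extracted with TRIzol LS and made into rRNA-depleted libraries with the Ovation SoLo system, per the labels' protocols. Libraries were grouped by the genotype in their labels into Patr1 and esgTS, 3 replicates each. The labels do not say how the Patr1 genotype changes the gene, and whether the replicates were collected on different days is not given in the sources used here.

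The submitters' processing notes name cutadapt 2.9, STAR 2.7.3a, SAMtools 1.10, Subread 2.0.0 with featureCounts, and DESeq2, without their order or settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and reads of overlapping genes cannot be assigned with certainty. The deposited counts are raw reads per gene with a gene length in bases, per the file headers. The deposited comparison table holds normalized values per library, a signal that equals the raw count times 1 constant per library, as tested on the tables. That table also holds the authors' log2 fold changes with their standard errors, Wald statistics (a score) and p-values with adjusted p-values, per the file headers. Only the raw counts entered the tests here, and values from the authors' table are named as such.

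Library totals ran from 2035676 to 2958607 reads over 17806 named genes, with 10885 to 11832 genes detected per library. A count of 3 reads, used as the floor of detection, was 1.01 to 1.47 CPM per library. The common biological coefficient of variation was 8.5%. Beyond the named genes the count table held 1 row with no gene name, which took 0.00226%, 0.00283% and 0.00296% of reads in the Patr1 libraries and at most 3.38e-05% in the esgTS libraries. That row was kept out of library sizes and tests. There were 5 gene names altered into dates in the table, which were tested but are not named in the text. Pairs of libraries within a genotype differed by more than sampling noise (chi-square per degree of freedom 2.57 to 4.50 over 6 pairs), which does not tell biological from technical spread; the 6 libraries were counted as separate samples as the labels number them.

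The comparison of Patr1 with esgTS used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter by group, and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes. Gene lists were tested with camera from limma 3.58.1 on log CPM (prior count 2) at a preset correlation of 0.01, adjusted over the 20 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. There were 22 lists: 16 by gene symbol and 6 by symbol pattern, of which 5 were primary (progenitor, enterocyte identity, digestive enzymes, enteroendocrine, P-body and mRNA decay). Of 402 listed symbols, 397 were matched; the unmatched were eIF4E-T, LSm2, LSm6, CAPRIN and dec-1, and hoka was matched as CG13704. Gene synonyms, overlaps and chromosomal order were taken from the BDGP6 annotation, without its coordinates. Overlap is mentioned where at least 20% of a named gene's exon bases lie in another gene. Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 made the remaining tables and the plots.

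The lists, the test and the rule for named genes were fixed before the data were examined. The rule took Patr-1; esg, Dl, N, nub, pros and me31B; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, leaving out rRNA, tRNA, snRNA, snoRNA and mitochondrial genes; and the members with the smallest p past the threshold in each list, up to 3 for a primary list and 2 for another, or the most abundant 1 where none passed. It gave 64 genes, of which 58 passed. Of these, 1 is not reported here. Other list members named beside their list's counts, the genes of the families described in the closing part, and Mhc were picked after their values were seen.

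The test was checked on 5 simulated data sets drawn from the means and library sizes of these samples, with 200 changed genes each among 7809 to 7818 tested genes. It recovered 67.2% of genes changed 1.5-fold, 83.2% of those changed 2-fold, 98.8% at 4-fold and 100% at 8-fold. Of 900 calls, 6.1% were false (3.8% to 10.5% per data set), and 0 had the wrong sign. Camera was run on 1 separate simulated data set, in which only the enterocyte identity genes were raised, each by 1.5-fold. It called that list (camera adjusted p = 4.4e-27) and 0 of 19 others. All members moved one way there, whereas the real list moved both ways. Far fewer genes were changed in these simulations than passed in the real comparison, and genes were drawn independently. The rates and the list result may therefore differ in the real data. The alternatives were DESeq2 1.42.0, RLE, upper-quartile and no scaling factors, no filter and a stricter one (5 CPM in 3 libraries), leaving out rRNA, mitochondrial and small RNA genes, robust fitting, the replicate number as a block, a test against a fold change of 1.5, an adjusted p of 0.01, and leaving out each library in turn. P-values measure the spread between these 6 libraries, which may be technical in part. Exact intervals (95%) and floors cover counting error only, because reads without molecular identifiers are not independent molecules.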

Results

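RNA was sequenced from intestinal progenitor cells of adult female Drosophila melanogaster. The progenitors, stem cells and their undifferentiated daughters, were sorted by GFP from dissected gastrointestinal tracts of 100 flies per replicate kept at 29 °C for 6 days. There were 2 genotypes, labelled Patr1 and esgTS, with 3 libraries each. The table held counts for 17806 named genes, and library totals ran from 2035676 to 2958607 reads. Patr1 replicates 1, 2 and 3 held 2035676, 2866705 and 2364686 reads, and the esgTS replicates 2856583, 2958607 and 2627978. Libraries of the same genotype correlated at 0.977 to 0.989 across genes (log CPM), and libraries of different genotypes at 0.888 to 0.896. The stated purpose of the series was to find RNAs that depend on P-bodies, the cytoplasmic granules that hold repressed mRNAs and decay factors. All fold changes below are Patr1 over esgTS.

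The transcript of Patr-1, a decapping activator of P-bodies, was 6.16-fold lower in the Patr1 libraries, at 35.9 ± 3.38 CPM against 220.1 ± 12.2 (mean ± SD, n = 3 each). Its level was 35.8, 32.5 and 39.3 CPM in Patr1 replicates 1, 2 and 3, and 206.7, 222.9 and 230.6 CPM in the esgTS replicates. The log2 fold change was -2.62 with a standard error of 0.10 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.56e-09). The mRNA of me31B, the DEAD-box helicase of the same granules, stood at 223.9 ± 14.0 CPM in Patr1 and 216.5 ± 7.83 in esgTS (n = 3 each, edgeR adjusted p = 0.64). The progenitor transcription factor gene esg had 644.9 ± 82.7 and 657.2 ± 41.9 CPM (edgeR adjusted p = 0.839). Dl, the Notch ligand made by stem cells, was 1.38-fold higher (log2 0.46 ± 0.09 SE, edgeR adjusted p = 0.0012), and its receptor N was 1.32-fold higher (log2 0.40 ± 0.09 SE, edgeR adjusted p = 0.00307). The enterocyte POU-domain factor nub rose 2.78-fold, from 37.1 ± 11.3 to 103.3 ± 10.5 CPM (edgeR adjusted p = 1.73e-05). The enteroendocrine homeodomain factor pros was at 45.0 ± 4.19 CPM in Patr1 and 41.6 ± 7.33 in esgTS (edgeR adjusted p = 0.515).

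**Figure D1:**
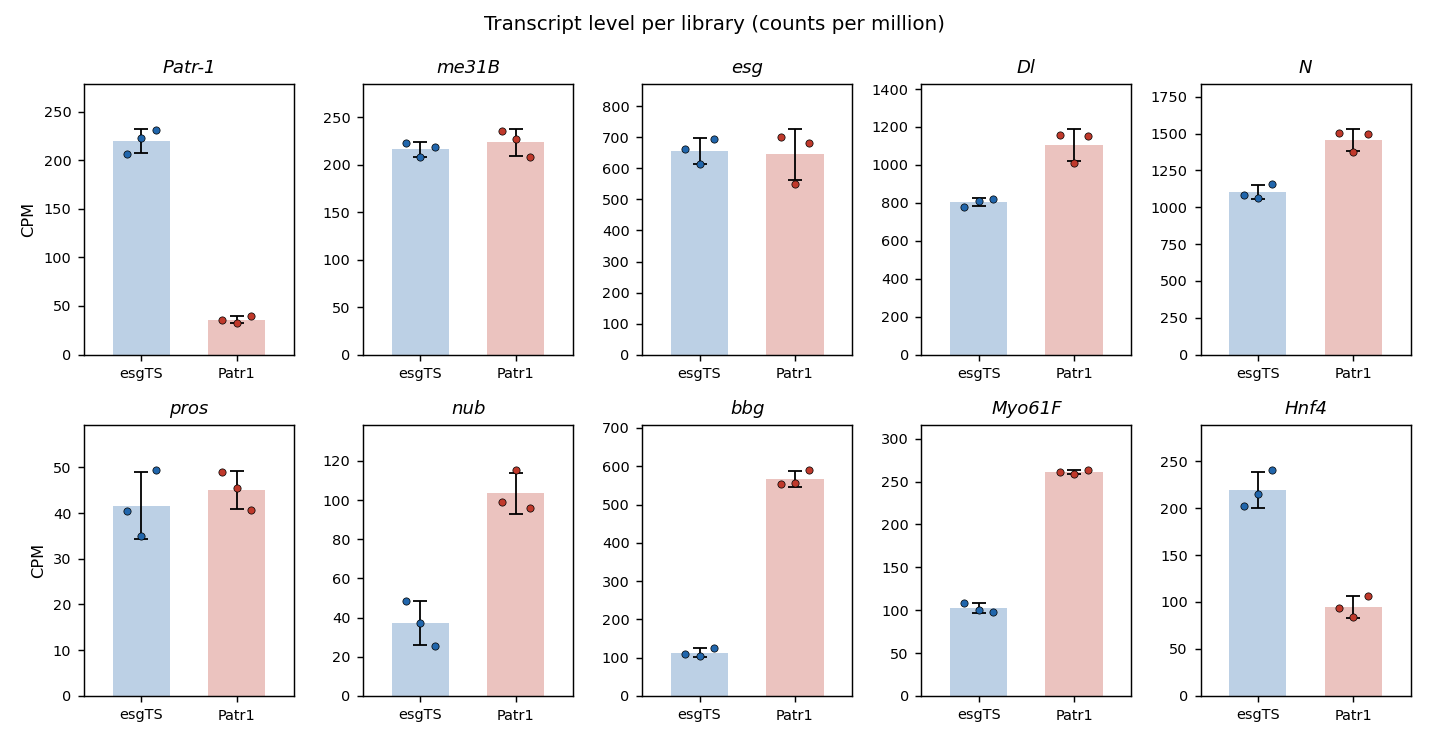
Transcript level in CPM (library-size-scaled reads, y axis) of 10 genes in the esgTS and Patr1 libraries (x axis); bars are means, error bars are the SD, and points are the 3 libraries of each genotype. Patr-1 lies at 32.5 to 39.3 CPM in the Patr1 libraries and at 206.7 to 230.6 CPM in the esgTS libraries, while esg overlaps between genotypes.

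The genotypes differed in many transcripts. Of 7927 genes tested, 3914 (49.4%) passed an edgeR adjusted p of 0.05, 2018 of them higher and 1896 lower in Patr1. Large changes were mostly rises: 184 genes were over 8-fold higher and 30 over 8-fold lower, by fitted fold change. Of those 184 rises, 15 had 0 reads in the esgTS libraries and 52 had 1 to 3. Counted from group read totals instead, with each total raised to at least 3 reads, 189 rises and 30 falls were over 8-fold. This is another measure than the fitted fold change, so the counts of rises are not directly comparable. The groups did not overlap in 4540 genes (57.3%), where 3 against 3 libraries give 10% by chance. The median change among called genes was 0.65 in absolute log2, and 1203 genes (643 higher, 560 lower) passed a test against a fold change of 1.5.

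The largest rises were in genes with almost no reads in esgTS. Shawl, a potassium channel gene, was at 82.0 ± 2.46 CPM in Patr1 and had 0 reads in all 3 esgTS libraries, which makes it at least 232-fold higher (against 3 counts over the group). The serpin gene Spn77Bb (71.5 ± 7.53 CPM), the protease homologue sphinx1 (28.5 ± 5.97) and lncRNA:CR43942 (22.2 ± 3.08) likewise had 0 esgTS reads, and were at least 202-fold, 80-fold and 64.2-fold higher. Reads of sphinx1 cannot be told apart with certainty from those of its near-identical neighbour sphinx2. A second serpin gene of the same cluster, Spn77Bc, had 587 reads in Patr1 and 1 in esgTS, a ratio of 698 (exact 95% counting interval 125 to 27600). The largest falls were in lncRNA:CR46123, with 1 read in Patr1 and 167 in esgTS (141-fold lower, exact 95% counting interval 24.9 to 5580), and in the tektin gene Tektin-C, with 3 and 260 reads (72.9-fold lower, 24.7 to 356). CG12502 had 2 and 106 reads (44.6-fold lower, 12.0 to 373). CG13375 fell from 101.6 ± 11.6 to 2.23 ± 0.41 CPM, the beta-alanine synthase gene pyd3 from 63.3 ± 5.84 to 2.44 ± 0.69, and the neuropeptide gene Ptth from 15.7 ± 0.77 to 0.66 ± 0.32. The edgeR adjusted p-values of these 11 genes ran from 1.31e-09 (CG13375) to 2.73e-05 (CG12502), and the 3 libraries of one genotype lay above all 3 of the other for each. These intervals and bounds cover counting error only.

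**Figure D2:**
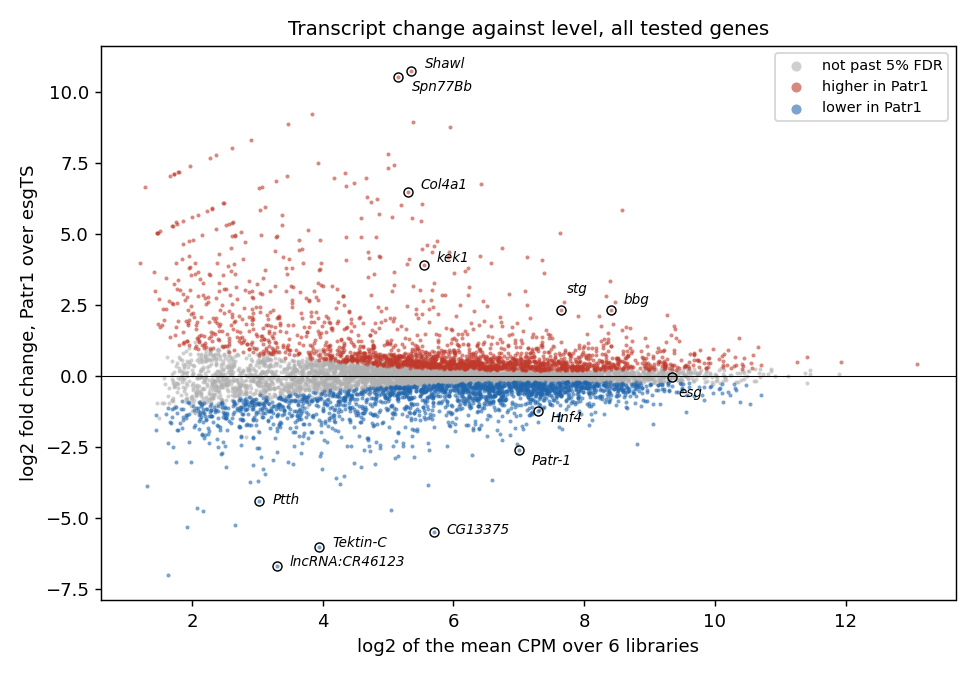
Log2 fold change (Patr1 over esgTS, y axis) against the log2 of the mean CPM over 6 libraries (x axis) for 7927 tested genes; each point is a gene, red for the 2018 higher and blue for the 1896 lower past a 5% false discovery rate, with circled genes named. Points above 8 on the y axis include genes with 0 esgTS reads, whose fitted fold change depends on the prior count.

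Markers of the progenitors themselves moved both ways. Of 25 progenitor genes, 8 rose, 5 fell and 12 did not pass the test, with the same counts when adjusted over the list alone. The BMP-binding protein gene cv-2 rose from 78.1 ± 4.41 to 220.4 ± 7.82 CPM (2.82-fold, edgeR adjusted p = 2.83e-08), and the zinc-finger factor gene sna from 23.4 ± 1.87 to 64.0 ± 5.11 (log2 1.46 ± 0.13 SE, edgeR adjusted p = 1.54e-06). The zinc-finger homeodomain gene zfh2 fell from 1758 ± 129 to 927.0 ± 137 CPM (log2 -0.92 ± 0.12 SE, edgeR adjusted p = 3.87e-05). The other risen genes were Dl, N, Sox21a, spdo, chn and E(spl)m7-HLH, and the other fallen ones were klu, mira, E(spl)mbeta-HLH and E(spl)mgamma-HLH. Notch target genes of the E(spl) complex appeared on both sides. The list as a whole had a median log2 fold change of 0.07 and did not stand apart from other genes (camera with a preset correlation of 0.01, adjusted p = 0.64 over 20 lists).

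More enterocyte identity genes rose than fell. Of 14 tested, 8 rose and 3 fell; adjusted over the list alone, 8 rose and 4 fell. The brush border gene bbg rose 5.02-fold, from 113.0 ± 11.1 to 566.3 ± 20.7 CPM (edgeR adjusted p = 2.21e-09). The class I myosin gene Myo61F rose 2.55-fold, from 102.3 ± 5.62 to 261.3 ± 2.2 CPM (edgeR adjusted p = 4.57e-08). The smooth septate junction genes mesh, Ssk and Tsp2A rose with nub, mex1 and CG13704, by log2 0.86 (Ssk) to 1.48 (nub). The nuclear receptor gene Hnf4 fell 2.33-fold, from 219.2 ± 19.6 to 94.6 ± 11.7 CPM (edgeR adjusted p = 1.39e-06), and the myosin gene Myo31DF and the lipase gene Lip4 were also lower (log2 -0.53 and -1.56). The median log2 fold change was 0.94. The camera adjusted p was 0.447 with the preset correlation and 0.989 with an estimated one, whereas fry, which asks whether the members move one way on balance without comparing them with other genes, gave 2.22e-06.

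More digestive enzyme genes, which mature enterocytes express, also rose than fell. Of 25 tested, 12 rose, 2 fell (Jon25Biii and Lip4) and 11 did not pass, and the counts were the same when adjusted over the list alone. The maltase gene Mal-A1 rose from 5.05 ± 1.67 to 24.9 ± 8.62 CPM (log2 2.27 ± 0.32 SE, edgeR adjusted p = 8.97e-05). The amylase gene Amy-d was at 8.05 ± 0.75 CPM against 1.93 ± 1.21 (log2 2.06 ± 0.42 SE, edgeR adjusted p = 0.00149), though its reads are not separable with certainty from those of the near-identical Amy-p, nor those of alphaTry from betaTry. Lip4 fell from 31.7 ± 2.97 to 11.01 ± 5.49 CPM (edgeR adjusted p = 3.75e-04). The list median was 0.36, with a camera adjusted p of 0.447 (0.989 with an estimated correlation). The number of risen members was 5 without esgTS replicate 1 and 7 without esgTS replicate 2. The number of fallen members was 1 with DESeq2 and without Patr1 replicate 2 or 3 or esgTS replicate 1, and 4 without Patr1 replicate 1 or esgTS replicate 2.

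Enteroendocrine genes split evenly, with 7 higher, 7 lower and 12 not past the test among 26 (7 and 8 when adjusted over the list alone). The synaptotagmin gene Syt4 rose from 1.04 ± 0.67 to 56.8 ± 6.01 CPM (log2 5.69 ± 0.28 SE, edgeR adjusted p = 1.32e-08). The proneural gene sc rose from 35.8 ± 3.52 to 98.9 ± 7.77 CPM (edgeR adjusted p = 5.33e-07), and the peptide hormone gene ITP from 289.0 ± 7.56 to 447.3 ± 37.6 (edgeR adjusted p = 6.61e-05). The secretory regulator dimm, the peptide genes AstA and CCHa1, and mirr were also higher. In replicates 1, 2 and 3, CCHa1 was at 24.7, 17.8 and 5.74 CPM in Patr1 and 6.56, 4.98 and 1.15 in esgTS, which overlap, and AstA at 19.2, 17.5 and 11.03 against 7.25, 1.66 and 0.38; NPF and Tk, which did not pass, were likewise lowest in replicate 3 of both genotypes. Orcokinin, 7B2, Pal2, svr, nSyb, tap and Ptx1 were lower. The median log2 fold change was -0.22 and the mean 0.27, and the tests differed in sign as well, with camera pointing down (adjusted p = 0.967) and fry up (adjusted p = 0.479). Fewer members fell in some alternatives: 3 with DESeq2, 4 without Patr1 replicate 2, 2 without Patr1 replicate 3, 4 without esgTS replicate 2 and 3 without esgTS replicate 3.

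**Figure D3:**
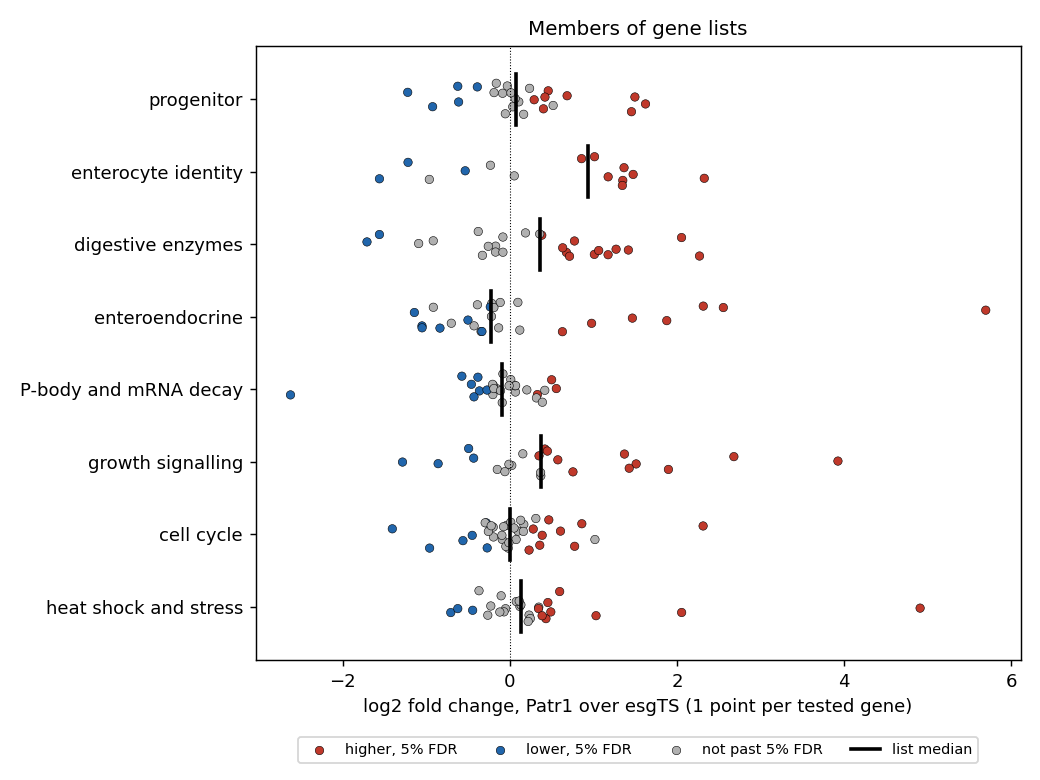
Log2 fold change (Patr1 over esgTS, x axis) of the tested members of 8 gene lists (y axis); each point is a gene, red or blue where it passed a 5% false discovery rate, and black lines are list medians. The enterocyte identity list has the highest median, 0.94, and the enteroendocrine median is -0.22.

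Among 28 genes of P-bodies and mRNA decay, Patr-1 had the largest change. Besides it, 6 fell (DCP2, AGO1, Rga, twin, Upf1 and smg), 3 rose (Ge-1, LSm1 and Pop2) and 18 did not pass, with the same counts when adjusted over the list alone. The CCR4-NOT deadenylase genes moved apart: Pop2 rose from 129.9 ± 5.56 to 183.9 ± 10.8 CPM (log2 0.50 ± 0.08 SE, edgeR adjusted p = 2.32e-04), and twin fell from 176.8 ± 9.32 to 131.1 ± 6.13 (log2 -0.43 ± 0.08 SE, edgeR adjusted p = 7.65e-04). The list median was -0.09 (camera adjusted p = 0.629), and 5 members rose without Patr1 replicate 1. Of 13 stress granule genes, 1 rose and 3 fell, also when adjusted over the list alone. Imp, an mRNA-binding protein gene, rose from 835.7 ± 78.6 to 1424 ± 170 CPM (edgeR adjusted p = 1.20e-04). TBPH, the fly TDP-43 gene, fell from 99.1 ± 9.89 to 63.2 ± 5.51 (edgeR adjusted p = 3.13e-04), as did lark and caz. That list had a camera adjusted p of 0.629; without Patr1 replicate 1, 2 members rose, and without Patr1 replicate 3, 5 fell.

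More growth signalling genes rose than fell, with 11 of 22 higher and 4 lower (the same adjusted over the list alone). The EGFR antagonist kek1 rose from 5.81 ± 1.27 to 87.4 ± 15.2 CPM (log2 3.93 ± 0.19 SE, edgeR adjusted p = 1.40e-08). The insulin receptor gene InR rose from 347.2 ± 16.5 to 935.1 ± 76.1 CPM (log2 1.43 ± 0.09 SE, edgeR adjusted p = 1.33e-07). All 3 genes of the JAK/STAT cytokines, upd1, upd2 and upd3, were higher, by log2 2.68, 1.37 and 1.51, together with the pathway's target Socs36E and receptor dome. The levels of upd2 overlapped between genotypes, at 197.8, 78.04 and 140.8 CPM in Patr1 against 23.47, 41.85 and 94.98 in esgTS (edgeR adjusted p = 0.0121). Egfr, nkd, Thor and Mmp1 were lower. The list median was 0.37, and the camera adjusted p was 0.291 (0.989 with an estimated correlation), against 0.00865 from fry.

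Cell cycle genes showed no shared direction: of 36, 9 rose and 6 fell (7 and 6 adjusted over the list alone), with a median log2 fold change of 0.00 (-0.03 to 0.03 across scalings) and a camera adjusted p of 0.968. The Cdc25 phosphatase gene stg rose 4.97-fold, from 66.7 ± 23.0 to 332.4 ± 32.6 CPM (edgeR adjusted p = 5.87e-07). Incenp, of the chromosomal passenger complex, fell from 128.9 ± 6.43 to 66.5 ± 5.67 CPM (edgeR adjusted p = 4.07e-06). PCNA, dpa, RnrL, RnrS, Orc1, aurB, Bub1 and pav were also higher, and CycB3, CycD, polo, Klp61F and feo were lower. Of 5 immune genes tested, the recognition gene PGRP-SD rose from 14.2 ± 5.60 to 38.4 ± 8.71 CPM (edgeR adjusted p = 4.90e-04), while the receptor gene PGRP-LC fell from 300.7 ± 11.5 to 184.6 ± 15.4 (edgeR adjusted p = 2.37e-05) and pirk was also lower. The counts were the same adjusted over the list alone, the camera adjusted p was 0.629, and 1 member fell without Patr1 replicate 2. Of 27 heat shock and stress genes, 9 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.521). GstD5, a glutathione transferase gene, rose from 1.79 ± 0.83 to 54.4 ± 0.99 CPM (edgeR adjusted p = 1.30e-08), and the glutathione synthesis gene Gclc from 159.5 ± 10.4 to 241.3 ± 21.4 (edgeR adjusted p = 1.45e-04). None of the 6 Hsp70 genes passed the edgeR test, at an unadjusted p of 0.05 or with DESeq2 either, and 6 members of the list fell without Patr1 replicate 1.

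Marker genes of other cell types showed a few large rises, and none of the 4 lists with enough tested members passed camera. Of 12 visceral muscle genes, 4 rose and 1 (how) fell: the projectin gene bt rose from 6.73 ± 1.68 to 61.8 ± 10.8 CPM (edgeR adjusted p = 1.39e-07) and the Z-disc gene Zasp52 from 100.3 ± 1.15 to 252.9 ± 34.9 (edgeR adjusted p = 5.66e-07), with sls and Msp300, whereas the muscle myosin gene Mhc was at 8.14 and 6.55 CPM (edgeR adjusted p = 0.469). Of 6 hemocyte genes, the type IV collagen genes Col4a1 (0.83 ± 0.27 to 78.1 ± 21.1 CPM, edgeR adjusted p = 1.92e-08) and vkg (1.51 ± 0.32 to 46.7 ± 13.6 CPM, edgeR adjusted p = 1.58e-07) rose, and crq and srp fell. Of 4 germline genes, 3 rose, with vas at 16.1 ± 3.14 CPM against 0.46 ± 0.17 (edgeR adjusted p = 1.32e-06; 25% of its exon bases overlap solo) and piwi at 578.6 ± 275 CPM (784.7, 684.6 and 266.6 in replicates 1, 2 and 3) against 186.8 (152.2, 205.0 and 203.4; log2 1.63 ± 0.29 SE, edgeR adjusted p = 6.22e-04). Of 5 Malpighian tubule genes, Irk1 (6.85 ± 2.35 to 20.2 ± 1.76 CPM; 61% of its exon bases overlap CG46310) and Alp4 (1.46 ± 1.07 to 6.59 ± 1.79 CPM) rose and Picot fell. Of 5 trachea and neuron genes, btl rose from 53.1 ± 3.97 to 87.6 ± 13.6 CPM (edgeR adjusted p = 3.75e-04), and the neuronal gene elav fell from 149.9 ± 14.8 to 91.7 ± 4.88 (edgeR adjusted p = 5.27e-05; 28% of its exon bases overlap lncRNA:enrr), as did nSyb. Of 2 fat body genes, neither passed the edgeR test, at an unadjusted p of 0.05 or with DESeq2 either, and the more abundant, sug, was at 11.5 ± 1.59 and 16.2 ± 5.79 CPM (edgeR adjusted p = 0.165, and 0.0372 without esgTS replicate 3, over a range of 0.0372 to 0.604 in 15 alternatives). Adjusted over each list alone, the counts of rises and falls were 4 and 1 for muscle, 2 and 3 for hemocytes, 4 and 0 for germline, 2 and 1 for tubule and 1 and 3 for trachea and neurons. The camera adjusted p-values were 0.447 (muscle), 0.927 (hemocyte and tubule) and 0.521 (trachea and neuron), and the trachea and neuron list had 1 fall with DESeq2 and without Patr1 replicate 3, esgTS replicate 2 or esgTS replicate 3, and 2 rises without Patr1 replicate 3 or esgTS replicate 1.

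**Figure D4:**
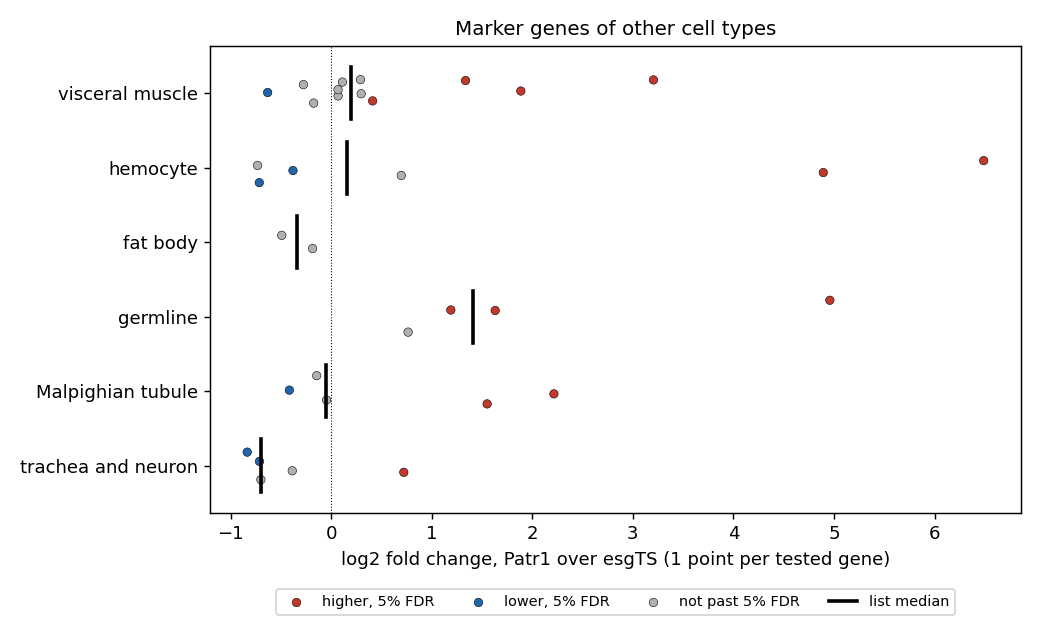
Log2 fold change (Patr1 over esgTS, x axis) of the tested marker genes of 6 other cell types (y axis); each point is a gene, red or blue where it passed a 5% false discovery rate, and black lines are list medians. Col4a1 (6.49) and vkg (4.89) lie far from the other hemocyte genes, whose list median is 0.16.

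Few members of the housekeeping groups passed the test. Of 84 genes taken as cytosolic ribosomal protein genes by symbol pattern alone, 0 rose and 4 fell past the edgeR threshold. The counts were 0 and 6 at an unadjusted p of 0.05, 0 and 2 with DESeq2, and 0 and 0 adjusted over the list alone. RpL24-like fell by 0.41 and RpLP0-like by 0.33 on the log2 scale (edgeR adjusted p = 0.0029 and 0.0166). Whether these like-named genes encode ribosomal proteins was not checked. Without Patr1 replicate 1 the list had 29 falls and a camera adjusted p of 1.77e-04, against 0.291 with all libraries (0.989 with an estimated correlation, which was 0.85); the falls numbered 1 without Patr1 replicate 2, 8 without esgTS replicate 2 (camera adjusted p = 0.00687), and 2 without esgTS replicate 1 or 3. The call for RpLP0-like was lost with DESeq2 and without Patr1 replicate 1 or 2 (adjusted p 0.111, 0.053 and 0.0719, in a range of 0.00634 to 0.111). Of 57 nuclear genes of oxidative phosphorylation, 4 rose and 4 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.968), among them ATPsynbeta (log2 -0.48, edgeR adjusted p = 0.00283) and UQCR-11L (log2 -1.38, edgeR adjusted p = 0.00453). With DESeq2 that list had 2 rises and 2 falls, and its rises numbered 1 or 2 without Patr1 replicate 2 or 3 or esgTS replicate 1 or 2; without esgTS replicate 1 its falls numbered 2. Of 16 mitochondrially encoded genes and 5 histone genes, 0 passed, also at an unadjusted edgeR p of 0.05, with DESeq2 and adjusted over the list alone (camera adjusted p = 0.967 for both); mt:CoI was at 776.0 ± 255 and 733.3 ± 114 CPM, and His3.3B at 890.1 ± 233 and 758.2 ± 76.0. Without Patr1 replicate 1, 5 mitochondrially encoded genes fell.

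Small and ribosomal RNAs depended on single libraries. Of 148 snRNA and snoRNA genes, 1 rose and 10 fell (0 and 1 adjusted over the list alone), with a median log2 fold change of -0.34. The camera adjusted p was 0.00359, and adjusted p = 0.989 with an estimated correlation. The call was also lost with fry (adjusted p = 0.5), without Patr1 replicate 3 (0.482) and without esgTS replicate 3 (0.0577), in a range of 1.85e-09 to 0.989. The falls numbered 55 without Patr1 replicate 1, 6 without Patr1 replicate 2, 4 without Patr1 replicate 3 (with 4 rises), 3 without esgTS replicate 3 and 4 with DESeq2. These genes took 0.311%, 0.233% and 0.132% of reads in the Patr1 libraries and 0.278%, 0.269% and 0.316% in the esgTS libraries. The strongest were snoRNA:Me28S-A771 (11.5 ± 2.38 to 3.48 ± 0.74 CPM, edgeR adjusted p = 7.01e-04) and snoRNA:Me18S-G1358b (9.66 ± 0.90 to 3.87 ± 1.5 CPM, edgeR adjusted p = 0.00475). Of 10 rRNA genes and pseudogenes, 2 rose and 0 fell, also at an unadjusted p of 0.05, with DESeq2 and adjusted over the list alone (camera adjusted p = 0.968). They were 28SrRNA-Psi:CR40596 (log2 1.03 ± 0.27 SE, edgeR adjusted p = 0.00706) and 28SrRNA-Psi:CR45851 (log2 1.52 ± 0.47 SE, edgeR adjusted p = 0.0166), repeated sequences whose reads are uncertain. The latter was lost without Patr1 replicate 1 (0.071) or esgTS replicate 2 (0.0652), in a range of 0.00214 to 0.071, and without Patr1 replicate 1, 7 rRNA genes fell.

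The authors' deposited table of the same comparison listed 9167 named genes, of which 3085 passed its adjusted p of 0.05, 1585 higher and 1500 lower in Patr1. In the authors' deposited table Patr-1 had a log2 fold change of -2.64 (adjusted p = 7.47e-68), nub 1.46, bbg 2.31, Hnf4 -1.23 and esg -0.05. Among 7491 genes tested in both, 3750 passed the edgeR test here and 2896 passed in the authors' deposited table. Both lists shared 2887 genes in the same direction, 99.69% of the deposited calls (exact 95% interval 99.41 to 99.86), and 0 in opposite directions; independent lists of these sizes would share 373 higher and 352 lower. Both rest on the same 6 libraries, so the overlap compares methods and is not a second experiment. With DESeq2 run here the share was 93.81% of 3085 deposited calls among 9167 genes.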

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

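Of the tests in this part, those of length and of the other splits were planned before their results were seen; the tests of chromosomal neighbours, other cell types and the enterocyte genes were chosen after. A signal in data outside the comparison came from the row of the count table that has no gene name. It held 197 reads over the 3 Patr1 libraries (46, 81 and 70) and 1 read over the 3 esgTS libraries, a ratio of 229 (exact 95% counting interval 40.6 to 9090), and its listed length was 2850 bases. What this feature is was not tested.

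The 3914 genes that passed between Patr1 and esgTS were set against all 10 splits of the 6 libraries into 3 and 3. The real split was the 1 split that called that many, and the highest of the others called 0 genes with edgeR, with 10 to 282 genes at an unadjusted p under 0.05. A total of 10 splits is too few for a share under 0.05. Every other split also put libraries of both genotypes on each side, so the genotype difference added to the spread within sides. Few calls were therefore likely in advance, and the 0 does not measure how many calls arise by chance.

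Rises over 8-fold outnumbered falls, 184 to 30. The trend of fold change with gene length across all tested genes was weak (Spearman rho -0.057) and does not account for this. After the median log2 fold change of 50 length bins was subtracted, 181 rises and 30 falls over 8-fold were left. Whether the risen genes themselves are unusually long or short was not tested. Genes moving with their chromosomal neighbours make up part of the excess of rises, as 36.4% of these risen genes had a risen neighbour. The 117 rises without a risen neighbour still outnumber the falls. RNA carried over from another cell type through the GFP sort stays open, because few marker genes could be tested. Over 8-fold rises were seen in 2 of 6 tested hemocyte genes (Col4a1 and vkg; 33.3%, exact 95% interval 4.3 to 77.7), 1 of 4 germline genes (vas) and 1 of 12 visceral muscle genes (bt). Col4a1 and vkg are neighbours on the chromosome, so the hemocyte interval, which takes genes as independent, may be too narrow. The hemocyte genes srp and crq fell, and NimC1, NimC2, eater and He had 0 reads in both genotypes. Of those too low to test, Hml and PPO1 had 15 and 8 reads in Patr1 against 2 and 0 in esgTS. In the same order, lz had 4 against 27 and PPO2 had 2 against 1. With no expression filter, 4 genes of the hemocyte list were called higher and 4 lower. Also open, and untested, is an effect of the lower Patr-1 transcript, which may act on these RNAs directly or through other genes, and any difference in genetic background between the genotypes.

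Of 14 tested enterocyte identity genes 8 rose and 3 fell, and of 25 tested digestive enzyme genes 12 rose and 2 fell. These lists hold 26 and 59 genes, and the other members had too few reads to test. Were more enterocytes, or more of their RNA, in the Patr1 sorts, the digestive enzymes would be expected to rise at least as much as the identity genes. The median log2 fold change was 0.36 for the tested digestive enzymes (bootstrap 95% interval over genes -0.17 to 0.77). For the tested identity genes it was 0.94 (-0.53 to 1.35). The difference, digestive minus identity, was -0.58 with an interval of -1.43 to 0.92. The interval spans 0, so a larger share of enterocytes or their RNA and a change within the sorted progenitors cannot be told apart from these lists. The identity genes Hnf4 and Myo31DF fell. Early, enzyme-poor stages of differentiation were not tested separately.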

How the results depend on the processing

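The normalizations, filters and tests listed with the methods, with each library left out in turn, were run on the count of called genes, the lists and the 64 named genes. No call of the edgeR test was reversed in any of them. The count of 3914 stayed within 3065 (DESeq2) to 4585 (no filter), except that a test against a fold change of 1.5 called 1203 genes, 643 higher and 560 lower, because it asks for larger changes, and an adjusted p under 0.01, a stricter threshold, left 2709. Leaving out a library gave 3258 to 3991 calls (1675 to 2072 higher, 1583 to 1919 lower), and 3128 to 3571 of the 3914 were among them. DESeq2 shared 2853 of the 3914. The share of higher calls was 47.3% with library size only and 55.2% with upper-quartile factors, and the median log2 fold change of all genes lay between -0.03 and 0.04. The medians of the cell cycle, oxidative phosphorylation, mitochondrial, rRNA and histone lists changed sign between scalings.

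No general pairing by replicate number was seen: deviations of same-numbered libraries from their group means correlated at 0.05, 0.20 and -0.04. Of 6 libraries, 2 correlated best with their own number. These 3 pairs cannot exclude an effect shared by same-numbered libraries on some genes. The peptide genes AstA, CCHa1, NPF and Tk were lowest in replicate 3 of both genotypes. With the replicate number as a block, 3901 genes passed.

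Fry called lists that camera did not: enterocyte identity (adjusted p = 2.22e-06), growth signalling (0.00865), visceral muscle (0.0318), hemocyte (0.000732) and, downwards, trachea and neuron (0.0172). It asks another question, whether members move one way on balance. The small RNA list lost its camera call in 3 alternatives and was not called by fry, and the ribosomal protein list gained one in 2, with the values given in the report; the cause was not tested. Of the named genes, 61 kept their side of the threshold in every alternative that gave a value; the others were RpLP0-like, 28SrRNA-Psi:CR45851 and sug. Counts of list members moved by over 1.5 times in 68 list-by-alternative values and stayed within that in 592, mostly in lists with few calls. The share of deposited calls recovered was 99.69% of 2896 with edgeR and 93.81% of 3085 with DESeq2, which covered more genes. Over the 7491 genes of the edgeR comparison, an alternative chosen after seeing the data, DESeq2 gave 94.3% of 2896. There DESeq2 called 2745 genes and edgeR 3750. With fewer calls than 2896, DESeq2 could not have recovered all of them. Why it called fewer was not tested. Changes of 1.5-fold were recovered in 67.2% of simulated genes, in data with far fewer changed genes than passed here. Smaller changes can therefore be missed, at a rate that the simulations do not fix for these libraries.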

Other observations

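The gene families in this part were chosen after the fold changes were seen, so their tests describe these libraries and are not independent evidence. Fisher's exact test also takes genes as independent, whereas many genes with large rises lay next to each other. The Spn77B genes lie in one run, and vkg with Col4a1 and Gr64a with Gr64f are neighbours. The p-values of the serpin, basement membrane and chemoreceptor families therefore count such a locus more than once. The large rises included genes of families best known from neurons. Of 30 tested genes for synapses and ion channels, 14 rose and 5 fell (14 and 3 with DESeq2). Over 8-fold, 7 of them rose (Shawl, Syt4, Snap25, dysc, Slob, cac and tipE). That is 23.3% against 2.3% of all genes (2-sided Fisher's exact test, adjusted p = 1.68e-05 over 12 families). The calcium channel gene cac went from 18.3 ± 7.99 to 309.0 ± 51.6 CPM and the scaffold gene dysc from 8.91 ± 0.66 to 204.8 ± 3.03 (n = 3 each). The pan-neuronal gene elav fell, from 149.9 CPM in the sorted esgTS cells to 91.7 in Patr1. The gene nSyb, with 35 reads in Patr1 and 74 in esgTS, also fell (edgeR adjusted p = 0.0358). In the trachea and neuron list, fixed beforehand, 0 of 5 tested genes rose over 8-fold, and the median log2 fold change was -0.70. That list, which holds elav and nSyb, had 1 fall with DESeq2. Of 47 axon guidance and adhesion genes, 23 rose and 14 fell (PlexB, DIP-alpha and Ten-m among the falls), and 11 rose over 8-fold, among them NetB, side, kon and 3 kekkon genes (Fisher's exact adjusted p = 7.9e-08).

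Several genes of secreted factors and matrix proteins were also among the large rises. Of 21 ligand genes, 11 rose and 5 fell, and 3 rose over 8-fold (Fisher's exact adjusted p = 0.0206). The FGF ligand gene ths went from 13 ± 4.91 to 752.0 ± 21.8 CPM, the Toll ligand gene spz from 60.4 ± 3.67 to 611.8 ± 76.1 and the FGF ligand gene bnl from 9.76 ± 0.39 to 94.1 ± 10.4 (edgeR adjusted p = 2.96e-10, 9.02e-10 and 5.96e-09). In the basement membrane family of 12 genes, 5 rose and 3 fell; Mmp2 joined Col4a1 and vkg over 8-fold, from 3.81 ± 1.16 to 93.0 ± 7.89 CPM, while Mmp1 fell from 208.6 ± 31.9 to 85.9 ± 9.57 (Fisher's exact adjusted p = 0.00464 for the family). Of 9 serpin genes, 4 rose and 3 fell (Spn27A, Spn55B and Spn42Da), and 3, all of the Spn77B cluster, rose over 8-fold (Fisher's exact adjusted p = 0.00224 for the 9 genes). Of 18 chemoreceptor genes, 6 rose and 7 fell (5 and 4 with DESeq2), with a median log2 fold change of -0.18. Over 8-fold, 5 of them rose: Or56a, Ir40a, Gr64a, Gr64f and Or19b (Fisher's exact adjusted p = 1.28e-04). More long non-coding RNAs fell than rose, with 47 higher and 78 lower of 225 (40 and 53 with DESeq2), although 20 rose over 8-fold (Fisher's exact adjusted p = 1.34e-06). Of 31 cytochrome P450 genes 6 rose and 15 fell, and of 25 glutathione transferase genes 16 rose and 5 fell. Of 26 piRNA pathway genes, 7 rose (vas, piwi and qin among them) and 8 fell, against 7 and 3 with DESeq2. For rises over 8-fold the Fisher's exact adjusted p was 0.565 for cytochrome P450 genes and 0.145 for both glutathione transferase and piRNA pathway genes. Integrins (3 of 5 higher, 0 lower with edgeR, also at an unadjusted p of 0.05 and with DESeq2) and UDP-glycosyltransferases (6 higher and 6 lower of 17) had Fisher's exact adjusted p-values of 1.00 and 0.087.

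Genes risen over 8-fold lay next to each other more often than in shuffled gene orders. Among 7896 tested genes placed on a chromosome, 41 pairs of neighbours in that order were both risen, against a median of 4 and a maximum of 15 in 10000 shuffles (permutation p = 1e-04, the smallest the shuffles can give). Without overlapping spans or shared family names there were 33 pairs, against a median of 3 and a maximum of 12 (permutation p = 1e-04, likewise the smallest). Those 33 still hold vkg with Col4a1, both type IV collagen genes, and CR6434 with Spn77Bb and with Spn77Bc. They are therefore not free of related genes or of genes from one run. The 41 pairs include vkg with Col4a1, a run from asRNA:CR43875 through Spn77Ba, Spn77Bb and CR6434 to Spn77Bc, and a run from Lsp1gamma through 4 long non-coding RNA genes and CG13405 to CG12483. No explanation was tested.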
